A study of Mus musculus with 8 samples.

How the data were processed

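The samples were 8 messenger RNA libraries of 1 immortalized mouse fibroblast line with the BRCA1-I26A mutation, 4 infected with a CRISPR lentivirus against Oct1 and 4 with a control lentivirus, labelled EV, which carried a nonspecific guide RNA per the description deposited with the table. Per the labels' protocols, cells grew for 2 days after infection, those positive for green fluorescent protein were sorted, and libraries were made from total RNA with a TruSeq messenger RNA kit. Whether counting used the strand of the reads was not given in the sources used here.

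The deposited counts are whole numbers per Ensembl gene and library, not normalized, in columns that the file headers name Treatment and Control with the numbers 0 to 3. Treatment was taken as Oct1_KO and Control as EV, and the column numbers match no replicate number of the labels, so libraries are named here by group and column. The genome build was mm10 and the tools included DESeq2, per the submitters' processing notes, and the aligner and the counting program were not given in the sources used here. The authors' log2 ratios between the groups, per gene and for 1 exon region per gene, are in the same table, per the file headers. The adjusted p-values beside these ratios were also deposited by the authors and are reported as theirs. Another 16 columns of normalized per-library values were not used. The deposited table lists 16110 genes, and 1 further line was emptied before this work, which with some named genes is not reported here. The listed genes had at least 13 counts over the 8 libraries. Starts in the deposited table are counted from 0, since 73.7% of genes matched to GENCODE M21 start 1 base below that annotation, and 1 was added for printing. By Ensembl identifier 15863 genes (98.5%) matched GENCODE M21, which gave gene types, overlaps and GC content. Exonic lengths were those of the deposited table.

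Total counts per library were 22710074, 21409412, 21011166 and 20707004 for Oct1_KO columns 0 to 3 and 22991702, 22445769, 20326108 and 19526731 for EV columns 0 to 3. Library pairs of 1 group differed by more than sampling noise, with chi-square values per degree of freedom from 2.99 to 9.52. Each library was counted as its own sample. Separate preparations of 1 culture could also exceed this noise, so these values do not show that the samples are independent. The biological coefficient of variation was 5.90%.

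Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14860 genes), libraries were scaled with TMM factors, and the quasi-likelihood F test compared Oct1_KO with EV with no covariate. P-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. Levels are CPM, counts relative to the library total scaled by the TMM factors, given as mean ± SD, and folds are those of the fitted model. The standard error (SE) of a log2 fold change is its size divided by the square root of F, an approximation. Principal components used log2 CPM with a prior count of 2. For Pou2f1 and Brca1 a two-sided exact permutation test of CPM was added.

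Before the data were examined, 35 gene lists were fixed, among them markers of other cell types. The 29 lists with at least 5 tested members were compared with the other genes by camera with a correlation of 0.01, adjusted over these lists, then by camera with an estimated correlation and by fry (limma 3.58.1). Each list is given with its changed members over all genes tested and adjusted over the list alone. The rule for the genes named in the text was also fixed before the data were examined, and genes named outside it are said to be chosen after their values were seen. It takes Pou2f1 and Brca1, the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 1 CPM and no overlap between the groups, and up to 4 changed members of each list with the smallest p, of which the text gives examples. Predicted genes and pseudogenes are counted but not named. Of the 154 genes this rule gave, 32 overlap a protein-coding gene, such as Pou2f1 with Cd247, Stra6 with Ccdc33, Avil with Tsfm, Cox6a2 with Itgad and Gys1 with Ruvbl2 on the opposite strand, and reads from such overlaps cannot be assigned with certainty.

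Alternatives fixed before the data were examined were the size factors of DESeq2, upper quartile factors, no low-count filter, a filter of at least 5 CPM in 4 libraries, each library left out in turn, DESeq2 1.42.0, limma-voom, a stricter threshold of 0.01, a fold of at least 2, a test against a fold of 1.5 and the removal of predicted genes. Chosen after seeing the data were fits without EV columns 0 and 3, without EV columns 1 and 2, and with a trend of each library on gene length and GC content removed (mgcv 1.9.3). Figures were drawn with matplotlib 3.10.9.

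The procedure was tested on simulated data for Oct1_KO against EV with 14860 genes, 200 of them changed. It recovered 62% of changes at a fold of 1.2, 84% at 1.5, 98% at 2 and 100% at 4, with 10 false calls (5.50% of calls). The changed genes were drawn from those above 1 CPM, with as many raised as lowered. In the data 59.4% of the tested genes changed, a setting that was not simulated. These rates therefore do not carry over to the 8823 calls or to genes below 1 CPM. A simulated list that moved was called and 0 of 30 unmoved lists were. The simulated genes varied independently of each other, so this result says nothing of lists whose members are correlated. In the data the estimated correlation of the called lists ran from 0.042 for extracellular matrix to 0.65 for cholesterol biosynthesis. An added length slope gave 5350 calls, and 26 calls were made after the trend was removed.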

Results

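Messenger RNA was sequenced from immortalized mouse embryonic fibroblasts (a permanently growing line of fibroblasts from mouse embryos) that carry the BRCA1-I26A mutation, an exchange in the RING domain of BRCA1, the part of the protein that acts in ubiquitin transfer. The cells were infected with a lentivirus that also marks infected cells with green fluorescent protein. In 4 libraries, labelled Oct1_KO, the virus carried a CRISPR guide RNA against Oct1, the transcription factor encoded by Pou2f1, and in the other 4, labelled EV, a nonspecific guide RNA as the deposited table describes its control. Each library held between 19526731 and 22991702 counts assigned to genes, and 14860 of 16110 listed genes had enough counts to be tested. Nothing in the labels says that the 4 libraries of a group came from separate infections, so the p-values measure only the spread between these samples.

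The comparison of Oct1_KO with EV asks which transcripts differ when Oct1 is targeted in cells with the mutant BRCA1, and the title of the series puts it in the setting of carbohydrate metabolism. Pou2f1 (ENSMUSG00000026565, mm10 chromosome 1, 165865154 to 166002678, minus strand) was lower in Oct1_KO by a small amount. Its level was 14.1, 15.1, 15.9 and 16.3 CPM in the 4 Oct1_KO libraries and 17.1, 17.3, 20.8 and 17.6 CPM in the 4 EV libraries. The log2 fold change was -0.25 (SE 0.080, edgeR adjusted p = 0.0155), and every Oct1_KO library lay below every EV library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The call was lost without EV column 2 (log2 -0.18, adjusted p = 0.0602) and without Oct1_KO column 0 (-0.21, adjusted p = 0.0574), and also after removal of a gene length and GC trend (-0.13, adjusted p = 0.0970). Counts over a whole transcript do not show whether it was edited, and the guide's target site was not given in the labels. Brca1 (ENSMUSG00000017146, chromosome 11, 101488764 to 101551955, minus strand) was at 57.3 ± 3.07 CPM in Oct1_KO and 64.3 ± 3.87 CPM in EV (SD, n = 4 each), a log2 fold change of -0.17 (SE 0.055, adjusted p = 0.0156). Its groups overlapped (exact permutation p = 0.0571), and the call was lost without Oct1_KO column 1 (-0.14, adjusted p = 0.0613) or EV column 2 (-0.13, adjusted p = 0.0542), and without EV columns 1 and 2 (-0.11, adjusted p = 0.124).

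The largest rise among the named genes was in Car3, a carbonic anhydrase, from 0.282 ± 0.156 CPM in EV to 33.9 ± 3.29 CPM in Oct1_KO (SD, n = 4 each), a fold of 117 (log2 6.87, SE 0.17). Its log2 fold change was 6.39 without EV columns 0 and 3 and 7.62 without EV columns 1 and 2. Islr rose 89.7-fold to 34.4 ± 3.66 CPM. Stra6, a membrane receptor for retinol-binding protein, rose 50.03-fold, from 0.226 ± 0.130 to 11.5 ± 1.17 CPM (log2 5.65, SE 0.21). The folds of Car3, Stra6 and C4b (0.431 CPM in EV) rest on few EV counts. Lbp, which binds lipopolysaccharide, rose from 1.55 ± 0.496 to 38.7 ± 2.76 CPM, and Igfbp5, a binding protein of insulin-like growth factors, from 1.44 ± 0.528 to 29.8 ± 2.55 CPM. The other 7 of the 12 largest rises were in Kcnj8, a subunit of a potassium channel (log2 4.79, SE 0.28, and 5.45 without EV column 1), Cldn10, a claudin (4.41, SE 0.28), C1qtnf7 (4.30, SE 0.17), Atp1b2, a subunit of the sodium-potassium pump (4.29, SE 0.24), Tmtc1 (4.24, SE 0.17), the complement gene C4b (4.14, SE 0.20) and Tmem178 (3.995, SE 0.26, and 4.70 without EV columns 1 and 2). C4b has the near-identical neighbour C4a, and reads of this pair cannot be assigned with certainty.

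**Figure D1:**
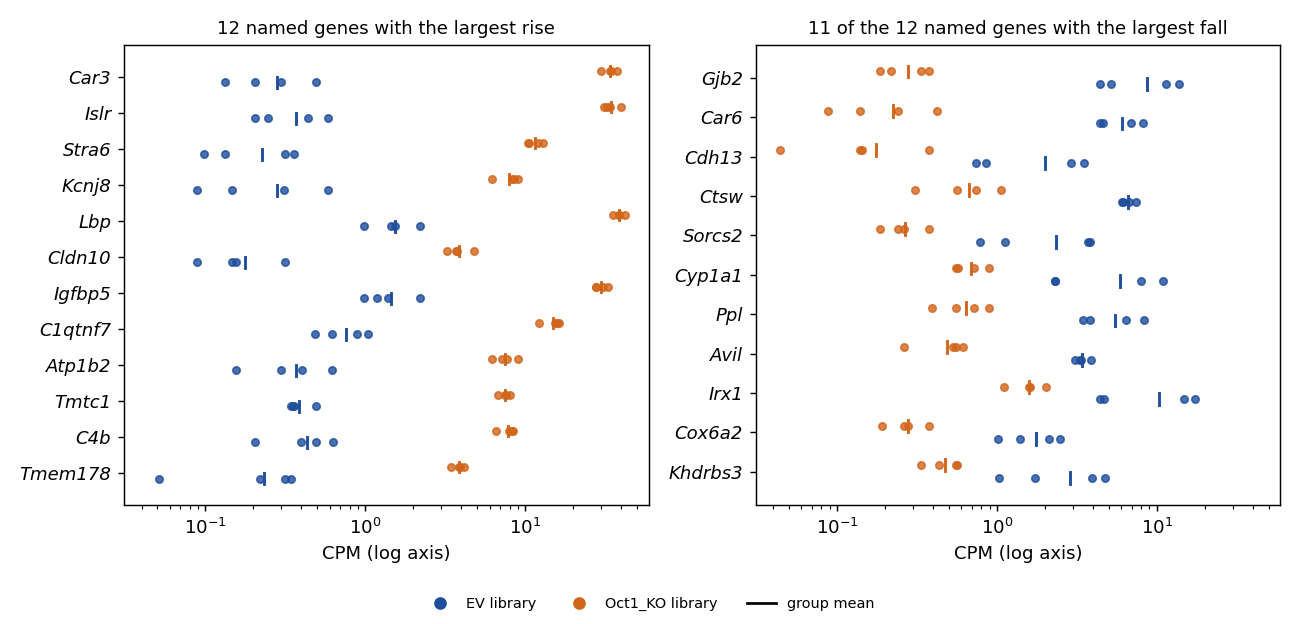
CPM (library-scaled counts) of the 12 named genes with the largest rise (left) and of 11 of the 12 with the largest fall (right) in Oct1_KO, on a log axis. Each point is 1 library and each tick the mean of 4 libraries. Car3 had a mean of 0.282 CPM in EV and 33.9 CPM in Oct1_KO, and Gjb2 8.68 CPM in EV and 0.280 CPM in Oct1_KO.

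Among the falls, Gjb2, a connexin of gap junctions, went from 8.68 ± 4.60 CPM in EV to 0.280 ± 0.0917 CPM in Oct1_KO (SD, n = 4 each), 30.5-fold lower, and Car6, a secreted carbonic anhydrase, from 6.04 ± 1.87 to 0.223 ± 0.148 CPM, 26.8-fold lower. The cathepsin gene Ctsw fell 9.89-fold, Ppl, which encodes the desmosome-associated periplakin, 8.56-fold, Avil, which encodes the actin-binding advillin, 6.91-fold and Cox6a2, a subunit of cytochrome c oxidase, 6.16-fold. Another 5 of the 12 largest falls were in Cdh13, an atypical cadherin (log2 -3.48, SE 0.62), Sorcs2 (-3.12, SE 0.54), Cyp1a1, a target gene of the aryl hydrocarbon receptor (-3.10, SE 0.51), the homeobox gene Irx1 (-2.68, SE 0.43) and Khdrbs3 (-2.57, SE 0.45). These 5, and Gjb2, Ppl and Cox6a2 less so, were uneven between the EV libraries. Irx1 was at 14.8 and 17.3 CPM in EV columns 0 and 3, at 4.70 and 4.44 CPM in EV columns 1 and 2 and at 1.59 ± 0.381 CPM in Oct1_KO. Without EV columns 0 and 3 the log2 fold changes were -1.52 for Irx1, -2.17 for Cdh13, -1.83 for Sorcs2, -1.52 for Khdrbs3, -4.08 for Gjb2 and -2.51 for Ppl, all 6 still past the threshold, with a highest adjusted p of 0.000547 for Cdh13. Cyp1a1 and Cox6a2 went the other way, with -1.75 (adjusted p = 7.45e-06) and -2.08 (adjusted p = 5.46e-05) without EV columns 1 and 2. Cox6a2 was at -3.01 without EV columns 0 and 3. Cdh13 also moved without Oct1_KO column 2, to -4.14.

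Over all tested genes 8823 changed at an adjusted p under 0.05, or 59.4%, of which 4478 rose and 4345 fell. Which direction held more genes depended on the scaling, with 4836 rises and 3907 falls with upper quartile factors, 4389 and 4448 with the size factors of DESeq2, and 3809 and 5253 after removal of the gene length and GC trend. Most changes were small, and 6141 of the changed genes (69.6%) differed by under 1.5-fold. At 2-fold or more 828 genes rose and 292 fell, and a test against a fold of 1.5 called 1027 rises and 378 falls. The 2-fold counts depended on the filter, with 452 rises and 95 falls at 5 CPM or more in 4 libraries and 997 and 427 with no low-count filter. In 7896 of the 14860 tested genes the 4 Oct1_KO values lay all above or all below the 4 EV values, an arrangement that chance gives for 2.86% of genes. On the 2-fold scale, 758 of the 828 rises and 244 of the 292 falls were also called without EV columns 0 and 3. Of the 292 falls, 51 (17.5%) differed by at least 2-fold between EV columns 0 and 3 and EV columns 1 and 2. The same held for 46 of the 828 rises (5.56%) and for 196 of all tested genes (1.32%).

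Genes of glycolysis and of glycogen metabolism rose more often than they fell. Of 24 tested genes of glycolysis and lactate export, 14 rose and 2 fell, and the same number, 16, passed when adjusted over the list alone. Aldoc, a fructose-bisphosphate aldolase, rose from 2.24 ± 0.832 to 16.7 ± 1.38 CPM (SD, n = 4 each), Ldhb, a lactate dehydrogenase subunit, from 17.9 ± 2.57 to 56.4 ± 4.74 CPM, and Slc16a3, an exporter of lactate, from 150 ± 3.52 to 250 ± 10.1 CPM. The glucose transporter gene Slc2a3 fell from 65.0 ± 2.77 to 27.4 ± 2.75 CPM. Among members chosen after their values were seen, the more abundant Aldoa and Ldha rose less (log2 0.19 and 0.37). Pkm, at 1621 CPM in EV, did not pass (-0.04). Of the same choice, Hk2 was the other fall (-0.50), and Slc2a1, another glucose transporter gene, rose (0.38). The list had a median log2 fold change of 0.21 (camera adjusted p = 0.00130, and adjusted p = 0.405 with an estimated correlation). All 11 changed members of the 14 tested glycogen genes rose (11 also adjusted over the list alone). They included the glycogen phosphorylases Pygl (0.446 ± 0.132 to 3.99 ± 0.574 CPM) and Pygb (1.42-fold), the glycogen synthase Gys1 (47.2 ± 1.11 to 70.9 ± 4.16 CPM) and Pgm2, a phosphoglucomutase (1.92-fold). The glycogen list had a median of 0.30 (camera adjusted p = 0.00861, and adjusted p = 0.405 with an estimated correlation), and its call was lost when genes needed at least 5 CPM in 4 libraries (median 0.18, adjusted p = 0.0983).

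Around pyruvate, the kinases of the pyruvate dehydrogenase complex Pdk2 and Pdk1 rose 3.04-fold and 2.36-fold, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, rose 1.69-fold and pyruvate carboxylase, Pcx, 1.54-fold. Of 15 tested genes of this list 7 rose and 4 fell, 11 adjusted over the list alone (camera adjusted p = 0.0921). In the TCA cycle 8 of 19 rose and 4 fell, 12 adjusted over the list alone, without a shift of the list (camera adjusted p = 0.598). Idh2 rose 1.498-fold, Mdh1 1.27-fold and Sdhc 1.26-fold, while Idh3a fell 1.28-fold. In the pentose phosphate pathway 3 of 11 rose and 4 fell, 7 adjusted over the list alone (camera adjusted p = 0.917), with H6pd, the glucose-6-phosphate dehydrogenase of the endoplasmic reticulum, 1.90-fold higher and Rpia 1.25-fold lower. The rise of Taldo1 in this list was lost after removal of the gene length and GC trend (log2 0.08, adjusted p = 0.0776).

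**Figure D2:**
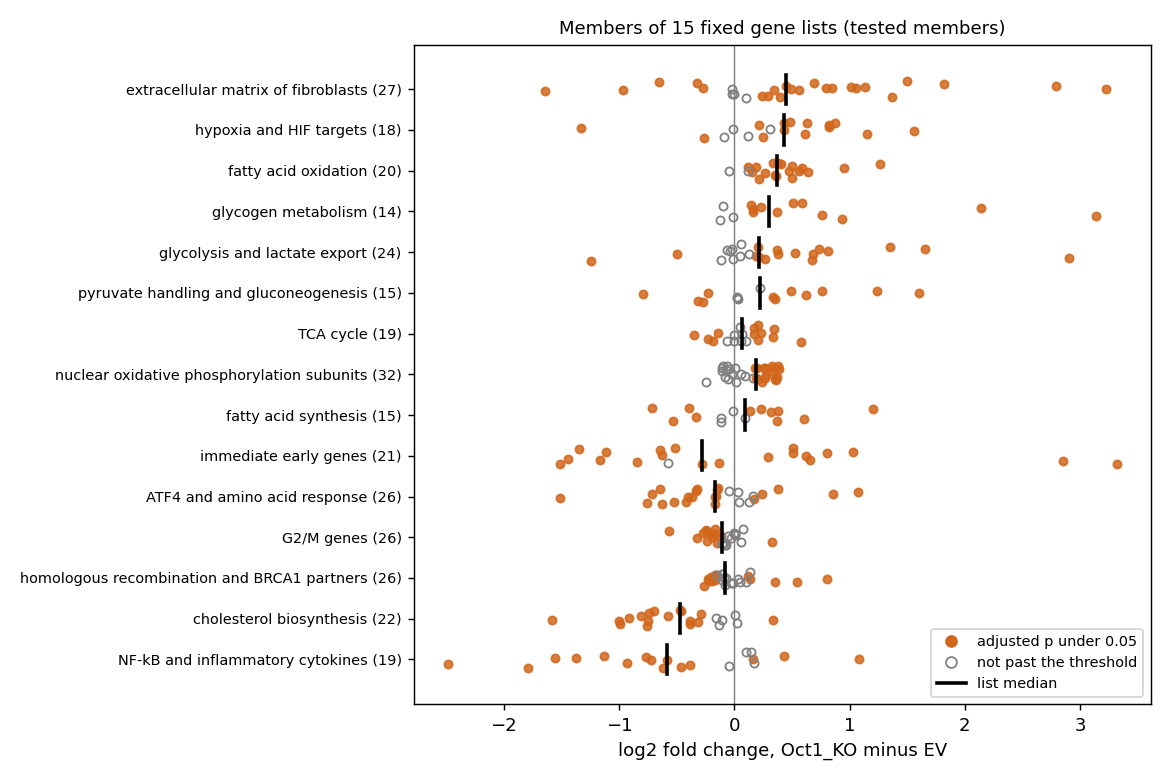
Log2 fold changes (Oct1_KO minus EV) of the tested members of 15 gene lists fixed before the data were examined, with the number of tested members in brackets. Each point is 1 gene, filled where its adjusted p was under 0.05, and the bar is the list median. The medians ran from -0.58 for NF-kB and inflammatory cytokines to 0.45 for the extracellular matrix of fibroblasts.

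Fatty acid oxidation rose nearly throughout, with 18 of 20 tested genes higher and 0 lower, again 18 adjusted over the list alone. Cpt1c and Cpt1a, of the carnitine palmitoyltransferase gene family, went from 16.9 ± 1.00 to 40.5 ± 2.31 CPM and from 44.5 ± 3.13 to 86.0 ± 2.02 CPM (SD, n = 4 each). The dehydrogenase gene Acadvl rose 1.56-fold and Decr1 1.48-fold. The list median was 0.37 (camera adjusted p = 1.89e-05, and adjusted p = 0.405 with an estimated correlation). Relative to the mean of all libraries, its median log2 level was -0.12 in EV columns 0 and 3 and -0.23 and -0.28 in EV columns 1 and 2. In Oct1_KO it ran from 0.16 to 0.23. Cholesterol biosynthesis moved down, with 16 of 22 tested genes lower and 1 higher, 17 adjusted over the list alone. Cyp51, which encodes a demethylase of lanosterol, fell from 193 ± 27.9 to 114 ± 6.74 CPM and Hsd17b7 from 30.4 ± 0.796 to 15.3 ± 1.58 CPM. Its median was -0.47 (camera adjusted p = 2.47e-05, and adjusted p = 0.594 with an estimated correlation). This list was also uneven within EV, where its median log2 level relative to the mean of all libraries was 0.41 and 0.43 in columns 0 and 3 and 0.12 and 0.05 in columns 1 and 2, against values from -0.27 to -0.18 in Oct1_KO.

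In fatty acid synthesis 7 of 15 tested genes rose and 4 fell, 12 adjusted over the list alone (camera adjusted p = 0.917). Fatty acid synthase, Fasn, fell from 515 ± 22.1 to 313 ± 16.7 CPM and ATP citrate lyase, Acly, 1.45-fold, while Acacb rose 2.30-fold and the desaturase gene Scd1 1.52-fold. Of 32 tested nuclear genes of oxidative phosphorylation 17 rose and 0 fell, 17 adjusted over the list alone, by small amounts such as 1.30-fold for Ndufa5 and Ndufa2, 1.28-fold for Cox7a2 and 1.25-fold for Atp5c1 (camera adjusted p = 0.154). Of 8 tested mitochondrially encoded genes 4 rose and 1 fell, 5 adjusted over the list alone (camera adjusted p = 0.598), and mt-Co1 went from 2623 ± 190 to 3071 ± 102 CPM. The single fall, of mt-Nd2, was lost without EV columns 0 and 3 (log2 -0.13, adjusted p = 0.0575), and the rise of mt-Nd4 without EV columns 1 and 2 (0.10, adjusted p = 0.102).

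Hypoxia and HIF target genes rose in 12 of 18 tested and fell in 2, with 15 changed when adjusted over the list alone. The mitophagy receptor gene Bnip3 rose 2.94-fold, the prolyl hydroxylases of collagen P4ha2 and P4ha1 1.76-fold and 1.55-fold, and the carbonic anhydrase gene Car12 1.83-fold (list median 0.43, camera adjusted p = 0.000744, and adjusted p = 0.405 with an estimated correlation). In the list of ATF4 targets and amino acid genes 5 of 26 rose and 16 fell, 21 adjusted over the list alone (camera adjusted p = 0.0881). Atf3 fell 2.85-fold, the amino acid transporter gene Slc7a5 1.69-fold and Shmt2 1.33-fold, while Pycr1, of proline synthesis, rose 1.81-fold. Of 23 tested NRF2 and oxidative stress genes 13 rose and 5 fell, 18 adjusted over the list alone (camera adjusted p = 0.121), among them the glutathione S-transferases Gsta4 (2.85-fold) and Gstm1 (2.19-fold), the ferritin heavy chain Fth1 (1.84-fold) and the heme transporter gene Slc48a1 (1.67-fold). Among 23 tested p53 targets 12 rose and 5 fell, 17 adjusted over the list alone (camera adjusted p = 0.324). Sesn1 rose 2.02-fold and the death receptor gene Fas 1.88-fold, and the kinase gene Plk2 fell from 550 ± 47.5 to 190 ± 10.7 CPM (SD, n = 4 each).

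The unfolded protein response list held 5 rises and 5 falls among 19 tested genes, 9 changes adjusted over the list alone (camera adjusted p = 0.917), each named one under 1.5-fold, such as Xbp1 (1.23-fold higher) and Hyou1 (1.14-fold lower). Heat shock proteins held 4 rises and 7 falls among 16, 11 changes adjusted over the list alone (camera adjusted p = 0.277), with Hsph1 1.36-fold and Hsp90aa1 1.38-fold lower and Hspb1 1.55-fold higher. Ribosomal protein genes held 5 rises and 5 falls among 31, 10 changes adjusted over the list alone (camera adjusted p = 0.780), with Rpl5 1.26-fold higher and Rpl10a 1.21-fold lower. Many ribosomal protein genes, Fth1 and Gapdh have processed pseudogenes of nearly the same sequence, and their counts are uncertain. Gapdh stood at 11.7 CPM in EV, beside 1621 CPM for Pkm, a pair chosen after its values were seen.

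Among cell cycle and DNA repair genes, each change named here was under 2-fold. Of 29 tested genes of the G1/S transition and replication 3 rose and 12 fell, 15 adjusted over the list alone (camera adjusted p = 0.231), with Mcm10 1.26-fold, Uhrf1 1.24-fold and Mcm5 1.23-fold lower and Rfc2 1.25-fold higher. Of 26 tested G2/M genes 1 rose and 12 fell, 13 adjusted over the list alone (camera adjusted p = 0.0881). Anln fell 1.48-fold, Kif23 1.21-fold and Prc1 1.18-fold, and the cyclin gene Ccnb2 rose 1.25-fold. Among 26 tested genes of homologous recombination and BRCA1 partners 5 rose and 8 fell, 13 adjusted over the list alone (camera adjusted p = 0.668). Rad51c rose from 13.1 ± 0.826 to 22.9 ± 0.690 CPM (SD, n = 4 each) and Bre 1.28-fold, while Fancd2 fell 1.201-fold and Mre11a 1.17-fold.

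Histone H2B genes, a class with Oct1 sites in its promoters, held 2 rises and 1 fall among 8 tested, 3 adjusted over the list alone (camera direction down, adjusted p = 0.954, and fry direction up, adjusted p = 0.661), and Hist1h2bc rose 1.42-fold. The other histone genes held 2 rises and 3 falls among 18, 2 adjusted over the list alone (camera adjusted p = 0.618), and Hist1h1c rose 1.46-fold. In these messenger RNA libraries the 26 tested histone genes of both lists had a median level of 0.708 CPM. At that level the counts cannot decide whether either class responded. Several of the histone calls were marginal. The falls of Hist2h2bb, Hist1h2ak and Hist1h4c (log2 -1.07, -0.98 and -1.38) were lost without EV column 0 (-0.85, -0.63 and -0.78, adjusted p = 0.0512, 0.104 and 0.116) and without Oct1_KO column 3 (-0.86, -0.84 and -1.19, adjusted p = 0.0513, 0.0636 and 0.0674). The fall of Hist1h2ak was also lost without Oct1_KO column 1 (-0.91, adjusted p = 0.0550) and that of Hist1h4c without Oct1_KO column 0 (-1.18, adjusted p = 0.0692). The rise of Hist2h2be (0.78) was lost without EV columns 1 and 2 (0.72, adjusted p = 0.0536). Histone levels differed between libraries of the same group, and the median of the H2B list ran from 0.61 in EV column 0 to -0.70 in EV column 3 on the log2 scale. All 3 tested genes of the POU family and its cofactors changed, 3 adjusted over the list alone, with Pou3f1 1.43-fold lower and Pou6f1 1.29-fold higher beside Pou2f1.

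Falls outnumbered rises among NF-kB targets and cytokines. Of 19 tested NF-kB targets and cytokines 12 fell and 3 rose, 17 adjusted over the list alone. The chemokine genes Ccl2 and Ccl20 went from 417 ± 11.2 to 191 ± 5.45 CPM and from 41.6 ± 8.53 to 7.44 ± 1.30 CPM (SD, n = 4 each), the cytokine gene Lif from 92.8 ± 6.26 to 31.6 ± 3.99 CPM, and Nfkb2 fell 1.54-fold. The list median was -0.58 (camera adjusted p = 2.47e-05, and adjusted p = 0.405 with an estimated correlation). Interferon response genes went both ways, with 6 rises and 7 falls among 24, 13 adjusted over the list alone (camera adjusted p = 0.572). Cxcl10 fell 2.53-fold, Rsad2 3.97-fold and Ccl5 2.60-fold, and Stat2 rose 1.48-fold. Immediate early genes also split, with 9 rises and 11 falls among 21, 20 adjusted over the list alone, a median of -0.28 and a mean of 0.02, which differ in sign (camera direction down, adjusted p = 0.713). Fos rose from 11.9 ± 1.63 to 86.4 ± 11.8 CPM and Fosb from 1.44 ± 0.270 to 14.4 ± 2.96 CPM, while Myc fell from 346 ± 24.9 to 159 ± 9.48 CPM.

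Genes of the fibroblast extracellular matrix rose in 18 of 27 tested and fell in 5, 23 adjusted over the list alone. Elastin, Eln, rose from 1.91 ± 0.178 to 17.9 ± 1.44 CPM, decorin, Dcn, from 234 ± 34.6 to 661 ± 33.8 CPM, and the collagen genes Col3a1 and Col1a2 from 1475 ± 199 to 3805 ± 112 CPM and from 2937 ± 348 to 5929 ± 103 CPM (SD, n = 4 each). The list median was 0.45 (camera adjusted p = 6.82e-06, and adjusted p = 0.201 with an estimated correlation). Contractile and TGF-beta genes held 7 rises and 9 falls among 20, 16 adjusted over the list alone (camera adjusted p = 0.598). Tgfbi rose 4.53-fold and Id3 1.84-fold, and the actin-binding genes Cald1 and Tagln fell 1.73-fold and 1.59-fold. The EV medians of this list were 0.15 and 0.17 in columns 0 and 3 and -0.06 and -0.11 in columns 1 and 2. Of 10 fibroblast identity markers 5 rose and 4 fell, 10 adjusted over the list alone (camera adjusted p = 0.713), with Pdgfra, a receptor of platelet-derived growth factor, 2.23-fold higher and the hyaluronan receptor gene Cd44 2.16-fold lower.

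Few markers of other cell types were expressed at a level that could be tested. Endothelial markers held 2 rises and 1 fall among 4, 3 adjusted over the list alone, and Kdr, a receptor of vascular endothelial growth factor, rose from 3.98 ± 0.573 to 31.95 ± 2.20 CPM (SD, n = 4 each) while Flt1 fell 1.51-fold. Adipocyte markers held 3 rises among 4, 3 adjusted over the list alone, with lipoprotein lipase, Lpl, at 204 ± 19.8 CPM in EV and 434 ± 22.8 CPM in Oct1_KO. Their EV medians were -0.93 and -0.69 in columns 0 and 3 and -0.16 and -0.41 in columns 1 and 2. The log2 fold change of Cebpa in that list was 0.69 without EV columns 0 and 3 and 1.64 without EV columns 1 and 2. Leukocyte markers held 3 rises among 4, 3 adjusted over the list alone, with Cd14 1.84-fold higher. The rises of Cd68 and Csf1r in that list (log2 0.32 and 0.25) were marginal and lost their calls without EV columns 0 and 3 (0.32 and 0.20, adjusted p = 0.0718 and 0.0553) and after removal of the gene length and GC trend (log2 0.17 and 0.14, adjusted p = 0.235 and 0.104). The call of Cd68 was also lost without EV columns 1 and 2 (0.32, adjusted p = 0.0894), with DESeq2 (0.31, adjusted p = 0.0813) and without any 1 of Oct1_KO columns 0, 1 and 3 and EV columns 0, 1 and 2 (0.25 to 0.34, adjusted p from 0.0505 to 0.121). Skeletal muscle markers held 1 rise among 2, or 2 adjusted over the list alone, with Mylpf 1.48-fold higher. Epithelial markers held 3 falls among 5, 3 adjusted over the list alone (camera adjusted p = 0.109). Krt14 fell from 300.0 ± 21.4 to 178 ± 18.0 CPM and Krt8 from 1.31 ± 0.591 to 0.105 ± 0.0619 CPM (log2 -3.58, and -2.91 without EV columns 0 and 3). Neural and glial markers held 3 falls among 4, 3 adjusted over the list alone, with Nes 1.70-fold and Map2 2.24-fold lower, and their EV medians were 0.53 and 0.63 in columns 0 and 3 and 0.19 and 0.20 in columns 1 and 2.

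**Figure D3:**
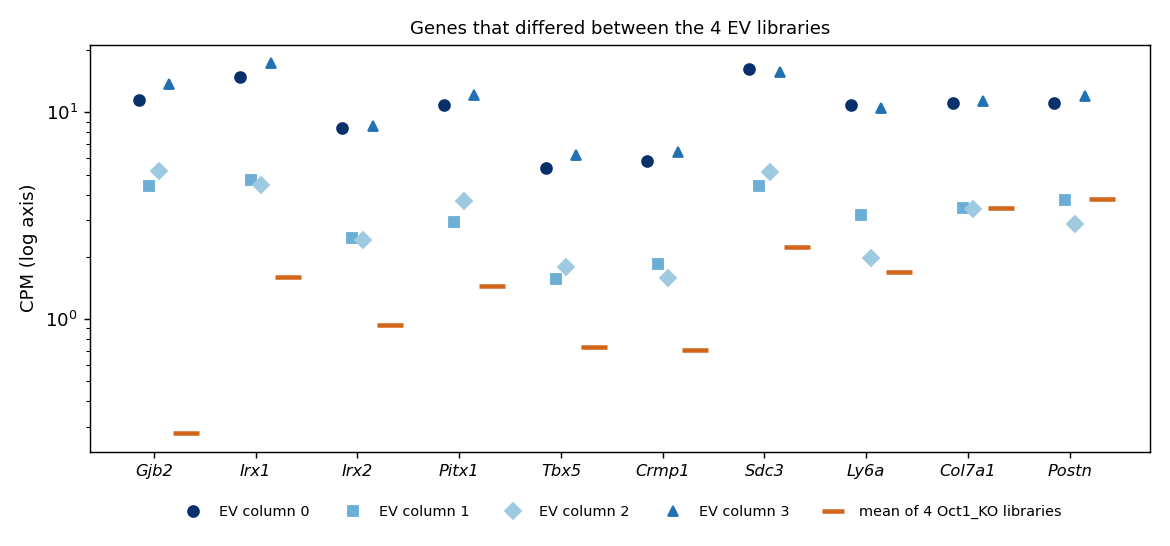
CPM (log axis) of 10 genes in the 4 EV libraries, with the mean of the 4 Oct1_KO libraries as a bar. The genes were chosen after their values were seen. EV columns 0 and 3 lie above EV columns 1 and 2 in each gene, as in Irx1 with 14.8 and 17.3 against 4.70 and 4.44 CPM.

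Each of the 7 list calls rests on the preset correlation of camera, and with an estimated correlation 0 of 29 lists passed (2 at an unadjusted p under 0.05), while fry, which asks whether a list moves one way on balance, called 17. The EV libraries parted along the second principal component (7.90% of the variance), with 12.8 and 19.2 for columns 0 and 3 and -14.4 and -17.5 for columns 1 and 2, while the first component (74.9%) parted Oct1_KO from EV.

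Of the 8823 genes called by edgeR, 8307 (94.2%) were also past an adjusted p of 0.05 in the same direction in the authors' deposited table, and 0 were past it in the opposite direction. Both sets of calls come from the same libraries, so this overlap compares methods and is no independent support for the calls. The authors' deposited table called 8581 genes, 4233 higher and 4348 lower, and gave Pou2f1 a log2 ratio of -0.25 (adjusted p = 0.0141) and Brca1 -0.17 (adjusted p = 0.0104). Its exon test was past 0.05 for 907 of 1333 genes with a reported exon result. For Brca1 the authors' deposited table named a region at mm10 chromosome 11, 101532017 to 101532160, with a log2 ratio of -1.26 between the groups (adjusted p = 1.85e-34). That region covers exon 6 of transcript Brca1-201, a coding exon at 101532020 to 101532159. For Pou2f1 the authors' deposited table reported no exon region.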

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

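The test of the gene length and GC trend used a setting chosen after seeing the data, with its bounds written before its result, and the other tests of this part were set before. Of 310 groups of 4 libraries (the CPM of 154 named genes in each group, and the library totals), 14 held 1 library far from the other 3, and chance alone gives about 15.5. In EV, Pou2f1 stood at 20.8 CPM in column 2 against 17.1 to 17.6 CPM in the others, and its call was lost without that library, as without Oct1_KO column 0. Also in EV, column 1 stood apart for Tmtc1 (0.492 CPM against 0.346 to 0.361), Pdk1 (24.3 against 21.7 to 22.03), Fasn (482 against 524 to 528) and Rsad2 (9.36 against 5.67 to 6.23), and column 2 for Fancd2 (49.9 against 47.8 to 48.1). In Oct1_KO, column 2 stood apart for mt-Co1 (3223 CPM against 3004 to 3038), Cyp51 (124 against 110.5 to 111.3), Rad51c (24.0 against 22.5 to 22.6), Mcm10 (80.3 against 75.9 to 76.2) and Fap (1.04 against 0.626 to 0.695). Column 1 of Oct1_KO stood apart for Kdr (35.2 CPM against 30.6 to 31.3) and Cebpa (6.95 against 5.39 to 5.51), and column 3 for Dcn (611 against 670 to 682).

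The first pattern weighed is the number of genes that changed between Oct1_KO and EV, 8823, beside a target gene that fell by 0.25 on the log2 scale. Chance assignment of libraries is argued against, since 1 of the 35 splits of the 8 libraries, the real one, gave as many genes. With edgeR the other 34 gave 0 at an adjusted p under 0.05 and between 28 and 2112 at an unadjusted p under 0.05. Each of those 34 mixes Oct1_KO and EV libraries, which puts the difference into the spread within groups. Counts of 0 were therefore likely beforehand and add nothing to the rank of 1 in 35. Removing the trend on gene length and GC content of each library left 87.2% of the calls in the same direction, which argues against that trend as the whole cause. A difference between the 2 sets of cultures other than the guide, such as infection, sorting or plating, cannot be told apart from the guide, because no label crosses the groups with an infection or a day and the spread within a group is small (biological coefficient of variation 5.90%). Loss of Oct1 stays open beside it, untested by any second guide.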

How the results depend on the processing

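The fits without 2 EV columns and with the trend removed were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers of the labels. The number of changed genes was 8063 to 8766 with 1 library left out, and 1120 at 2-fold or more or 1405 against a fold of 1.5, both stricter by construction. Rises outnumbered falls (4478 to 4345), but not with the size factors of DESeq2 (4389 to 4448), its own test (4220 to 4344) or the trend removed (3809 to 5253). Pou2f1 lost its call, with the cause not tested, without EV columns 1 and 2 (-0.18, adjusted p = 0.0874) and with the trend removed (-0.13, adjusted p = 0.0970). With 1 library left out it ran from -0.27 to -0.18, with adjusted p from 0.0139 to 0.0602. Against 7 lists called, 11 were called without EV columns 0 and 3, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 17 with fry, and 7 to 8 with 1 library left out. The glycolysis median stayed at 0.21 with an estimated correlation, where its adjusted p was 0.405, since this setting changes the test alone. With 1 library left out it ran from 0.18 to 0.23. Of the 35 splits of the libraries 19 gave at least 7 lists and the highest other split gave 13, so chance is not excluded for the number of lists. No gene named by the fixed rule and none of the 7 called lists turned its direction under the alternatives run. DESeq2 on the deposited counts called 8564 genes, 8561 of them also called in the authors' table.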

Other observations

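The gene groups of this part were listed after the main results were seen, and so were its tests, except the first test of small RNA genes and that of the Hox genes, whose bounds were set before their results. For those 2 tests, and for cells of another type, the value met the bound set against the explanation, and the reading as undecided was chosen after the value was seen. The genes named in this part were chosen after their values were seen. Complement genes rose in 10 of 13 tested and fell in 1 (11 changed adjusted over the list alone). The complement factor gene C3 went from 82.8 ± 24.3 to 452 ± 43.2 CPM (SD, n = 4 each), the regulators Cd55 and Serping1 rose 7.81-fold and 7.01-fold, and Masp1 fell 3.22-fold. Of 15 tested glutathione S-transferases 12 rose and 1 fell (13 adjusted over the list alone), with Gsta3 at 1.58 ± 0.569 CPM in EV and 22.9 ± 2.56 CPM in Oct1_KO and Mgst1 at 54.1 ± 5.71 and 189 ± 12.9 CPM. Of 13 tested genes of the insulin-like growth factor system 10 rose and 2 fell (12 adjusted over the list alone). Igfbp3 rose from 134 ± 34.3 to 885 ± 75.2 CPM, Igfbp2 from 3.44 ± 0.439 to 38.0 ± 4.75 CPM and the imprinted RNA H19 from 28.5 ± 7.89 to 150 ± 6.05 CPM, while the receptor gene Igf1r fell 1.503-fold. These counts are no test of the groups, since C4b, Igfbp5, Gsta4, Gstm1 and Stra6 were known to have risen when the groups were written.

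Of 15 tested retinoid genes 10 rose and 1 fell (11 adjusted over the list alone), with the reductase gene Dhrs3 at 28.3 ± 4.38 CPM in EV and 228 ± 19.96 CPM in Oct1_KO (SD, n = 4 each), the retinoic acid receptor gene Rarb 3.48-fold higher and Crabp1 4.15-fold lower. The metallothionein genes Mt1 and Mt2 fell, Mt2 from 26.5 ± 3.47 to 4.83 ± 0.407 CPM and Mt1 from 47.3 ± 6.75 to 17.5 ± 1.65 CPM, and with the zinc exporter gene Slc30a1 they were the 3 changed genes of 5 tested (3 adjusted over the list alone). Among cartilage and tendon genes 6 of 10 rose and 1 fell (7 adjusted over the list alone), with Fmod 3.48-fold higher and Sox9 1.52-fold lower. The aryl hydrocarbon receptor list holds the receptor gene Ahr itself beside targets. Of its 6 tested genes 4 fell, Ahr among them, and 1 rose (5 adjusted over the list alone). Cyp1b1 did not pass (204 ± 26.0 CPM in EV and 204 ± 11.7 CPM in Oct1_KO). Among the falls, the EV libraries ran from 6.49 to 16.5 CPM for Ahrr and from 58.8 to 94.5 CPM for Tiparp. The Oct1_KO means of these genes, 7.70 and 59.1 CPM, lay within those ranges, while those of Ahr and Cyp1a1 (70.5 and 0.686 CPM) lay below their EV libraries. In median absolute log2 fold change the metallothionein and zinc list lay at the percentile of 49.2 among 10000 matched random lists, the aryl hydrocarbon receptor list at 64.5, the cartilage and tendon list at 96.5, the retinoid list at 99.4 and the complement, transferase and growth factor lists at 100. The last 4 and the aryl hydrocarbon receptor list hold genes known to have changed when they were written. The metallothionein list and the cartilage and tendon list were also written after the main results were seen, so none of these percentiles is a test. Hox genes rose in 21 of 32 tested and fell in 1, Hoxc11 (22 adjusted over the list alone), with Hoxb13 1.98-fold and Hoxc8 1.67-fold higher. One hypothesis is that the groups hold different mixes of fibroblast subpopulations, but the median absolute log2 fold change of the Hox genes, 0.38, lay at the percentile of 91.3 among 10000 matched random lists, under the bound of 95. The hypothesis stays open, since a mix need not shift these genes more than others and no label gives the makeup of the cultures.

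The second pattern weighed is the difference between EV libraries. Among genes with at least 50 counts in EV column 0, 56 were at least 2-fold higher in column 0 than in column 1. Of these, 55 were higher in column 3 than in column 2. Their median log2 ratio of column 3 over column 2 was 1.24, which argues against counting noise for genes at this level. Depth is argued against by totals of 22991702 and 19526731 counts in columns 0 and 3 around 22445769 and 20326108 in columns 1 and 2 (a gap of -2.67 M counts, negative because the pairs overlap), and a gene length and GC trend by the 104% of the median left after its removal. The highest median ratio among 6 marker lists of other cell types was 0.41, in 5 epithelial genes, under the bound of 0.5 of that median, but other lists had as few as 2 tested members, so cells of another type are not excluded. A different share of 1 fibroblast subpopulation may also be the source, and stays open because the ratios spread 1.99 times as widely as counting error and replicate variation give, between the bounds of 1.5 and 3. Of the 56 genes, 37 were lower in Oct1_KO, 33 of them by at least 2-fold, and 1 was higher. Their median log2 fold change was -1.36. The same EV values enter both comparisons, so the 2 are not independent.

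The third pattern weighed is the difference in histone transcripts, which were higher in EV column 0 than in EV column 3 in 23 of 26 tested genes, with a median log2 difference of 1.22 and a median level of 0.708 CPM, while the histone medians in Oct1_KO were 0.14, -0.06, -0.07 and -0.45 in columns 0 to 3, so the spread is not one of EV alone. A change in the share of cells in S phase is argued against by the G1/S list, whose median difference was -0.012. The test of carry-over of RNA without a poly(A) tail gave a median of 0.14 over 177 genes annotated as small or miscellaneous non-coding RNA, under its bound, but these include segments of long RNAs and 170 overlap other genes, whose reads can fill their counts, so it decides nothing. In the 7 of these genes outside other genes the median was 0.94, with 6 higher in column 0 than in column 3. The difference was 2.77 for Rn7sk, 2.70 for Rny1, 2.30 for Rny3 and 0.94 for the ribosomal RNA gene n-R5-8s1. But 3 hardly differed, the small RNA gene Snord104 (0.03) and HOTAIRM1_5 (-0.13) and HOXB13-AS1_1 (0.19). The last 2 are segments of long RNAs and not small RNA genes. Rn7sk stood at 72.1 and 45.3 CPM in EV columns 0 and 1 and at 12.5 and 10.5 CPM in columns 2 and 3. Carry-over may account for part of the histone difference, as a hypothesis found and tested on the same libraries in few genes that did not all move.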
